A study of Danio rerio with 18 samples.

How the data were processed

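Whole tumours were extracted with Trizol and total RNA was made into libraries with Illumina protocols, per the labels' protocols. FastQC, Trimmomatic, STAR and DESeq2 and the genome build GRCz10 are named in the submitters' processing notes, without versions or roles. The annotation release and the strand setting are not given in the sources used here. The authors deposited a table of raw read counts for 27057 Ensembl genes in 18 libraries, as the table's own sheet name and its whole-number values show. It has 4 further entries for reads that were unmapped, mapped to several places, fell outside annotated genes or were ambiguous between genes. These name no gene and were kept out of library sizes and tests. Their joint share was 19.9% to 30.1% of reads per library, of which 9.46% to 17.4% fell outside genes and 1.94% to 3.08% mapped to several places. Each column was matched to its sample by the library name in the sample's description.

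Depth was 14973777 to 21191902 reads assigned to genes per library. Reads of near-identical gene copies may be split or lost where they map to several places, and without a stated strand setting overlapping genes cannot be separated, so values of gene copies are less certain. Gene names came from a reference table of Ensembl identifiers, which named 24020 of the 27057 genes. Zebrafish copies often carry the same human-style name there, and the identifier is printed wherever a name is not unique.

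Groups were set by the plasmid in the labels. The design of each test, the 27 gene lists, the alternatives and the rule for named genes were written before the data were examined. The lists held 631 names, of which 584 matched the reference table after ignoring case and, failing that, copy numbers and copy letters, with names that gave over 3 identifiers left out. This matching rule was set after the identifiers were seen and before any test. The gene crestin was not matched and is not analysed here.

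Genes were kept with edgeR's filterByExpr (count minimum 10, total minimum 15), which left 18731. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are sox10 minus mitfa tumours. Their standard errors were computed as the fold change divided by the square root of the F statistic. CPM are the deposited counts scaled here to 1000000 reads per library with TMM factors. On simulated counts for 18521 genes of this comparison, with 200 changed genes, the test made 123 calls of which 5 were false. It recovered 23.2% of 2-fold, 63.0% of 4-fold and 83.1% of 16-fold changes.

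A list score was the mean over members of log2 CPM with a prior count of 2, for lists with at least 4 members past the filter. Score differences were tested by a 2-sided exact permutation test over all 18564 splits of the tumours into 6 and 12, adjusted over 27 lists. Of 200 simulated scores with no difference, 6.5% had a p under 0.05. Lists were also compared with the other genes by camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and, beside it, with an estimated one. Between-tumour spread was the root mean squared distance, over all genes tested, from the mean of the tumour's own group, corrected for group size and compared by the same exact permutation test. Group means were not recomputed for each split.

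Named genes were, by the rule, a few set in advance, among them sox10, mitfa, crestin, braf and atad2. To these came the 6 highest and 6 lowest fitted fold changes among called genes with a gene name that is not a clone or accession name, a mean of at least 2 CPM and group medians (plus 0.5 CPM) at least 2-fold apart. Up to 2 called members with the smallest adjusted p were added from each list. The rule gave 60 genes, some of which are not reported here.

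Alternatives were DESeq2 1.42.0, limma with sample quality weights, dispersion without robust estimation, RLE and upper quartile factors, no filter beyond 1 count, a filter of 5 CPM in 6 tumours, a minimum of 2-fold, a replicate block, muscle, epidermis or fibroblast scores as covariates, other list scores, and each tumour left out. Alternatives chosen after seeing the data summed sox10 tumours 9 and 10 into 1 library, left out mitfa tumours 1 and 5, or took the share of reads outside genes as a covariate. For list scores the last used an exact permutation of residuals of the reduced model. Pairs of libraries were compared by the squared deviation of each gene's counts from their pooled ratio, divided by binomial noise, as a median over genes with more than 20 reads in the pair.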

Results

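RNA sequencing was performed on 18 whole tumours, labelled as melanoma, from zebrafish (Danio rerio) in a p53-deficient background. Fish received a plasmid at the 1-cell stage and were themselves the founder generation, so each fish is a mosaic of plasmid-bearing and plasmid-free cells. In 6 tumours the plasmid expressed BRAF V600E, an activated form of the BRAF kinase, from the promoter of mitfa, a gene for a transcription factor of the melanocyte lineage. In the other 12 the same oncogene was placed behind the promoter of sox10, a transcription factor gene of the neural crest that also marks glia. They are called mitfa tumours and sox10 tumours here, and the comparison asks how tumours started by the same oncogene under these promoters differ in gene expression. The labels number the tumours within each group and do not say how many fish they came from, so the p-values measure the spread between these samples. Sample numbers in the library names run separately by group, and a batch that follows the group cannot be excluded.

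The tumours had between 14973777 and 21191902 reads assigned to genes. Depth was 17781152 ± 1812818 reads (SD, n = 6) in mitfa tumours and 16898979 ± 1585857 reads (SD, n = 12) in sox10 tumours (2-sided exact permutation test, p = 0.306). Reads that fell outside annotated genes made up 10.8% ± 1.45 of all reads in mitfa tumours and 14.3% ± 1.999 in sox10 tumours (exact permutation p = 0.00194, adjusted p = 0.00776 over 4 such measures). Sox10 tumours 9 and 10 had much more similar counts than any other pair. The median squared difference of their counts was 2.42 times sampling noise, against 16.5 to 135 times for the other pairs. They differed by more than sampling noise and were kept as separate samples.

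Pigment cell transcripts were abundant in mitfa tumours and low in sox10 tumours, and glial and neural transcripts were abundant in sox10 tumours and low in mitfa tumours. Of 18731 genes tested, 4024 were higher and 4190 lower in sox10 tumours at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At least 2-fold differences among these were found in 3073 genes that were higher and 3262 that were lower. Called genes made up 43.85% of those tested, a share to set beside the counts of called list members below. In 1283 genes every sox10 tumour lay above every mitfa tumour, and in 919 every one lay below. Together these were 11.8% of the genes tested, where chance gives 0.0108%. The leading principal component held 43.9% of the variance and separated the groups. With the share of reads outside genes as a covariate, an alternative chosen after seeing the data, 2432 genes were higher and 2489 lower.

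**Figure D1:**
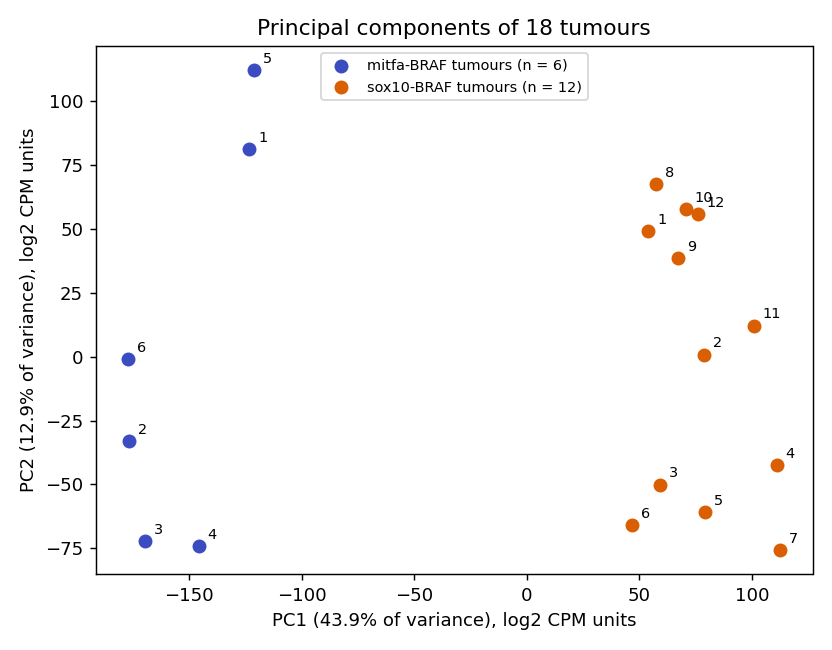
Principal components of log2 CPM (counts scaled to 1000000 reads per library) over 18731 genes, with PC1 and PC2 in log2 CPM units. Each point is a tumour, numbered within its group, and all 6 mitfa tumours lie at negative PC1 and all 12 sox10 tumours at positive PC1.

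Genes of melanin synthesis and melanosomes were among those that fell furthest in sox10 tumours. The 6 named genes with the lowest fold changes were pmela, which encodes a scaffold protein of melanosomes, TYRP1 (ENSDARG00000056151) and TYR, melanin-producing enzymes, SLC45A2, a melanosome transporter, MC1R, the melanocortin receptor of pigment cells, and uraha, an enzyme of urate breakdown. Expression of pmela in CPM, counts scaled to 1000000 reads per library, was 4385 ± 3696 (SD, n = 6) in mitfa tumours and 5.44 ± 1.83 (SD, n = 12) in sox10 tumours, a log2 fold change of -9.65 ± 0.47 (SE, edgeR adjusted p = 4.41e-11). TYR had 331 ± 243 CPM against 0.471 ± 0.234 CPM, and MC1R 97.0 ± 67.4 CPM against 0.160 ± 0.105 CPM. Of the 2 genes named MITF, the abundant one (ENSDARG00000003732) had 174 ± 33.5 CPM in mitfa tumours and 3.29 ± 2.95 CPM in sox10 tumours, a log2 fold change of -5.73 ± 0.53 (SE, edgeR adjusted p = 8.21e-08). The other (ENSDARG00000037833) had 3.12 ± 1.86 CPM and 5.13 ± 3.05 CPM (edgeR adjusted p = 0.196).

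All 3 pigment cell lists fell in sox10 tumours. In the melanocyte differentiation list 17 of 18 members tested fell and none rose, in the iridophore list 15 of 16 fell and none rose, and in the xanthophore list 11 of 16 fell and 1 rose. The counts adjusted over the list alone were the same numbers. TSPAN10, a tetraspanin of melanocytes, fell by 8.57 on the log2 scale, and pnp4a, a purine enzyme of reflective iridophores, by 6.82. In the xanthophore list slc2a11b, a transporter needed for yellow pigment cells, fell by 8.01, while 2 of its fallen members are TYRP1 copies that also stand in the melanocyte list. List scores, the mean log2 CPM of the members, differed by -6.48 for melanocytes, -3.48 for iridophores and -2.48 for xanthophores. Each had an exact permutation p of 5.39e-05, the smallest that 18564 splits can give (adjusted p = 0.000208). Against the other genes tested these lists were lower too, and with an estimated correlation the camera adjusted p was 0.0236, 0.00805 and 0.0461.

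Glial transcripts were high in all 12 sox10 tumours. In the Schwann and glia list 15 of 19 members rose and none fell (16 rose adjusted over the list alone). S100B, a calcium-binding protein of glia, had 4.23 ± 2.47 CPM (SD, n = 6) in mitfa tumours and 1311 ± 528 CPM (SD, n = 12) in sox10 tumours, a log2 fold change of 8.27 ± 0.54 (SE, edgeR adjusted p = 7.78e-10). The 4 members not called over all genes were EGR2, GLDN, PMP22 and a copy of FABP7, named after their values were seen. PMP22, a myelin protein of Schwann cells, had 79.1 ± 56.6 CPM in mitfa tumours and 45.3 ± 36.8 CPM in sox10 tumours (edgeR adjusted p = 0.161). The list score was 2.64 ± 0.223 in mitfa tumours and 7.41 ± 0.479 in sox10 tumours (exact permutation p = 5.39e-05, adjusted p = 0.000208). With an estimated correlation the camera adjusted p was 0.00768.

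Neural genes rose as well. The 6 named genes with the highest fitted fold changes were pou3f2a, SOX1 (ENSDARG00000069866) and SIX6 (ENSDARG00000031316), transcription factors of the developing nervous system and eye, nlgn3b, a synaptic adhesion protein, CDK5R1 (ENSDARG00000037916), an activator of the neuronal kinase CDK5, and ST8SIA5, a sialyltransferase of gangliosides. No mitfa tumour had a read of pou3f2a or CDK5R1. Their sox10 means were 14.97 ± 16.3 and 7.23 ± 2.41 CPM, at least 511-fold and 247-fold higher than the level that 3 reads over the whole mitfa group would give. SIX6 had 0.327 ± 0.219 CPM against 232 ± 173 CPM. In the neuronal list 13 of 14 members rose and none fell, also adjusted over the list alone. ELAVL3, a neuronal RNA-binding protein, had 0.809 ± 0.756 CPM (SD, n = 6) in mitfa tumours and 440 ± 151 CPM (SD, n = 12) in sox10 tumours, and its relative ELAVL4 had 0.591 ± 0.765 CPM against 48.8 ± 47.0 CPM. The neuronal score differed by 3.81 (exact permutation p = 5.39e-05, adjusted p = 0.000208). It was 5.78 and 5.93 in sox10 tumours 4 and 7, and 2.12 to 3.81 in the other 10. Transmitter neuron genes, a list written after most of its values had been seen, summed to 105 and 256 CPM in those 2 and to at most 36.2 CPM in the other 10. The neuronal list's camera adjusted p was 0.296 with an estimated correlation, against 0.000116 with the preset one.

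**Figure D2:**
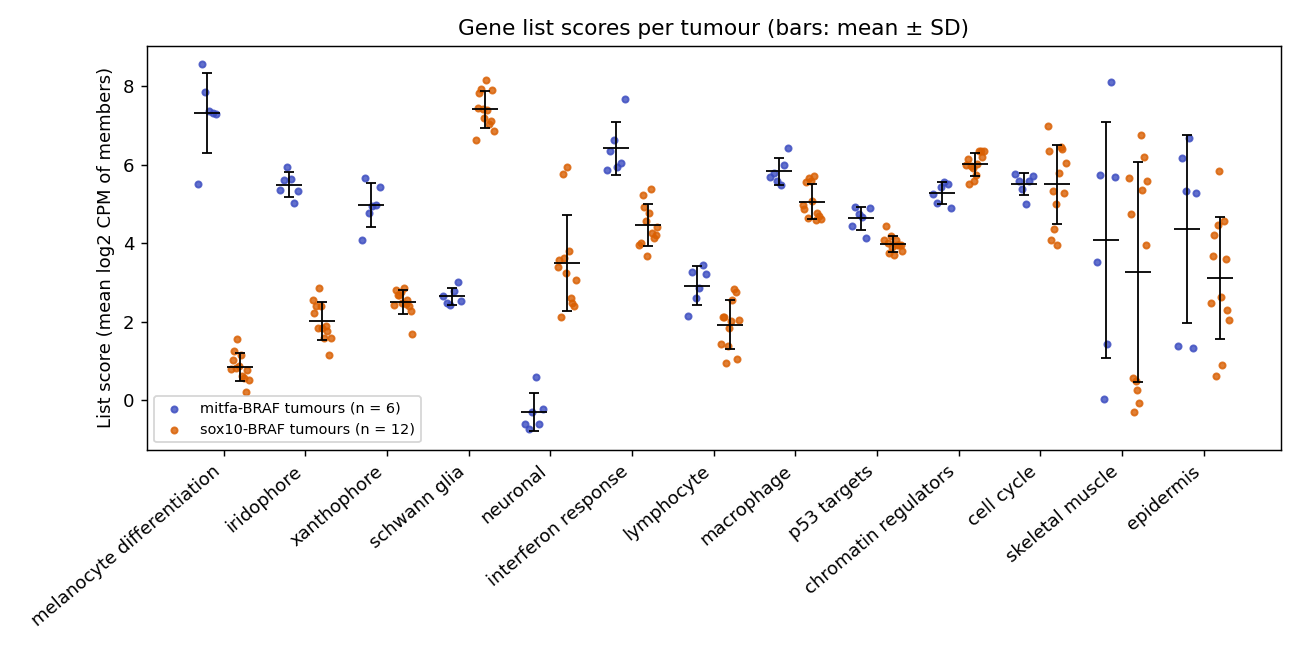
Scores of 13 gene lists, each the mean log2 CPM of its tested members, by tumour. Points are tumours (6 mitfa, 12 sox10), bars the mean and SD. Pigment cell scores are lower and glial scores higher in all sox10 tumours, while cell cycle, skeletal muscle and epidermis scores overlap.

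Neural crest factors moved in both directions. SOX10 itself had 478 ± 138 CPM (SD, n = 6) in mitfa tumours and 990 ± 278 CPM (SD, n = 12) in sox10 tumours, a log2 fold change of 1.05 ± 0.23 (SE, edgeR adjusted p = 0.00111). SOX9 (ENSDARG00000043923), a transcription factor of crest and glial precursors, rose from 7.42 ± 5.35 to 1199 ± 460 CPM. In contrast snai2, a repressor of epithelial genes in crest cells, fell from 143 ± 47.1 to 3.78 ± 1.71 CPM. Of 17 neural crest members, 6 rose and 7 fell (6 and 8 adjusted over the list alone). The crest score was lower by -0.72 (exact permutation p = 5.39e-05, adjusted p = 0.000208), but members scaled to equal variance gave -0.19 and no call (adjusted p = 0.202), and camera made none (adjusted p = 0.565). In the dedifferentiated and mesenchymal list 6 of 25 rose, 4 fell and 15 did neither, also adjusted over the list alone. CDH2, a cadherin of mesenchymal and neural cells, rose from 31.0 ± 18.9 to 426 ± 129 CPM. The largest rises in that list were both SOX9 copies (log2 fold changes 7.33 and 5.63), which also stand in the neural crest list. Next came CDH2 (3.78), which also stands in the Schwann and glia list. That list's rise is therefore not separate from theirs. The dedifferentiated and mesenchymal score was higher by 1.06 (exact permutation adjusted p = 0.00393), although its median fold change was negative (-0.26). Its call was lost with scaled members (0.42, adjusted p = 0.0922) and with the share of reads outside genes as a covariate (0.72, adjusted p = 0.153). Against other genes its camera adjusted p was 0.082.

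Targets of the MAP kinase pathway, which BRAF drives, did not move as a block. ETV1, an ETS transcription factor stabilised by that pathway, rose from 0.628 ± 0.395 CPM (SD, n = 6) to 384 ± 135 CPM (SD, n = 12), and SPRED3, a pathway inhibitor, from 0.0775 ± 0.0574 to 24.1 ± 11.3 CPM. In all, 5 of 21 members rose and 8 fell (5 and 9 adjusted over the list alone). DUSP6, a phosphatase that acts on ERK and was chosen after its values were seen, fell from 1154 ± 834 to 326 ± 182 CPM. The score difference was 0.20 (exact permutation p = 0.399, adjusted p = 0.514), and the median fold change of the members was -0.60. Zebrafish BRAF had 10.4 ± 6.30 CPM in mitfa tumours and 16.4 ± 5.02 CPM in sox10 tumours (edgeR adjusted p = 0.0812). Without mitfa tumour 4 its log2 fold change was 1.03 (edgeR adjusted p = 0.00547). The labels do not say from which species the BRAF of the plasmid came, so these counts are not a measure of the transgene.

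Both groups were in a p53-deficient background, so differences in p53 targets are no measure of p53 activity. Among these targets 8 of 19 fell and 1 rose, also adjusted over the list alone. GADD45A (ENSDARG00000104571), a stress-response gene, fell from 80.6 ± 72.0 CPM (SD, n = 6) to 3.13 ± 1.06 CPM (SD, n = 12), and cdkn1a, the cell cycle inhibitor p21, from 7.56 ± 2.48 to 1.08 ± 0.599 CPM. GADD45A was low in mitfa tumours 1 and 5 too, at 5.83 and 10.3 CPM. Its other copy (ENSDARG00000043581) was not called (log2 fold change -0.48, edgeR adjusted p = 0.181). The score differed by -0.65 (exact permutation p = 0.000269, adjusted p = 0.000808), with a camera adjusted p of 0.0546, and 0.218 with an estimated correlation. No cell cycle gene among 27 passed the threshold in edgeR, DESeq2 or limma, and 0 had an unadjusted p under 0.05 in edgeR. The score differed by -0.0043 (exact permutation p = 0.992), with a median fold change of 0.28. Cell cycle scores had an SD of 0.283 in mitfa tumours and 1.01 in sox10 tumours.

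Chromatin regulators were higher as a group in sox10 tumours. Of 62 members tested 31 rose and 1 fell, also adjusted over the list alone. KDM6B, a histone demethylase, rose from 75.6 ± 18.2 CPM (SD, n = 6) to 277 ± 94.4 CPM (SD, n = 12), a log2 fold change of 1.87 ± 0.25 (SE, edgeR adjusted p = 8.04e-06). ATAD2B, a bromodomain ATPase, rose from 29.8 ± 8.48 to 90.2 ± 28.1 CPM. Its relative ATAD2 had 51.3 ± 17.6 CPM and 56.5 ± 37.0 CPM, a log2 fold change of 0.14 ± 0.43 (SE, edgeR adjusted p = 0.811). The score differed by 0.74 (exact permutation p = 0.000108, adjusted p = 0.000364). The camera adjusted p was 1.05e-06, and 0.396 with an estimated correlation.

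**Figure D3:**
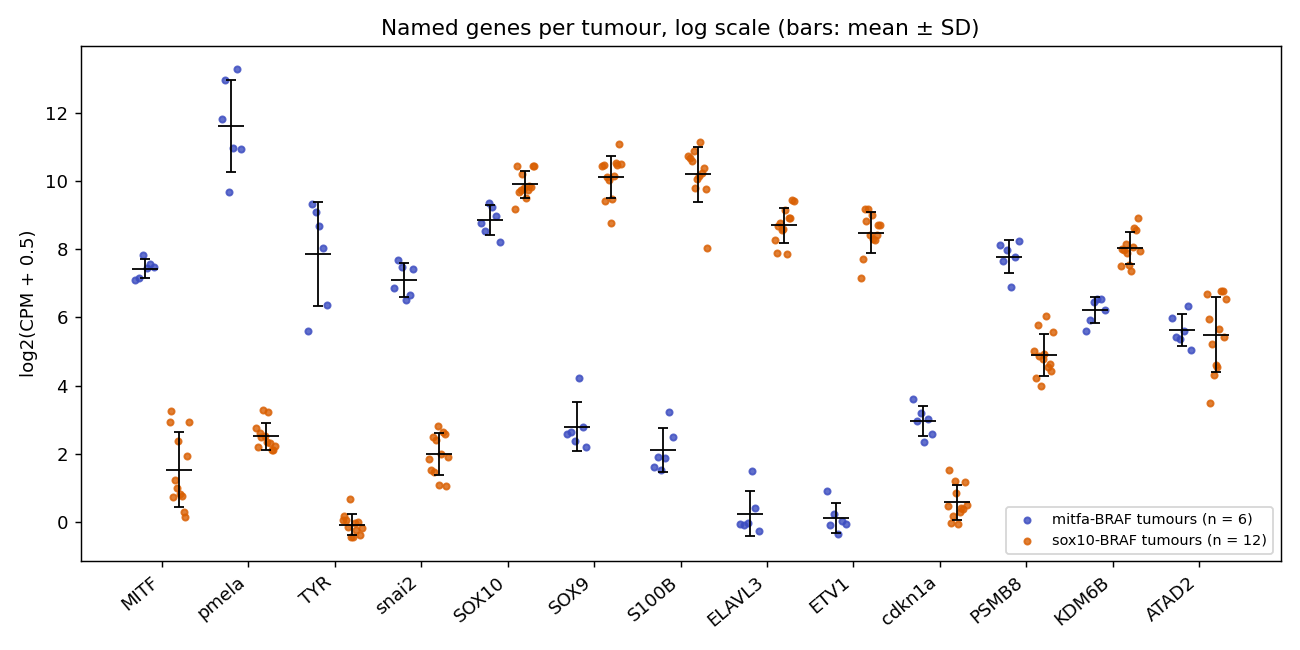
Expression of 13 named genes by tumour as log2(CPM + 0.5), a log scale. Points are tumours (6 mitfa, 12 sox10) and bars the mean and SD on that scale. MITF is ENSDARG00000003732 and SOX9 is ENSDARG00000043923. The groups overlap for ATAD2, and 11 of 12 sox10 tumours lie above all mitfa tumours for SOX10.

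Interferon response and immune cell transcripts were lower in sox10 tumours. Of 22 interferon response members 18 fell and none rose, also adjusted over the list alone. PSMB8, an immunoproteasome subunit, fell from 229 ± 66.0 CPM (SD, n = 6) to 32.1 ± 15.4 CPM (SD, n = 12), and mxa, an antiviral GTPase, from 104 ± 63.4 to 9.77 ± 4.86 CPM. In the macrophage list 13 of 22 fell and 2 rose (16 and 2 adjusted over the list alone). The 2 that rose, picked out after their values were seen, were csf1rb and apoeb, an apolipoprotein that glia also make. MPEG1 (ENSDARG00000043093), a pore-forming protein of macrophages, fell by 3.87 on the log2 scale, and by 3.01 without mitfa tumour 6. Its copies ENSDARG00000055290 and ENSDARG00000078569 had log2 fold changes of -1.10 and -1.68 (edgeR adjusted p = 0.0334 and 0.355). In the lymphocyte list 11 of 21 fell (12 adjusted over the list alone), among them cd28, a T cell costimulator, by 3.32, and ptprc, the pan-leukocyte antigen CD45, by 1.11. Score differences were -1.96 for interferon, -0.77 for macrophages and -1.003 for lymphocytes (exact permutation adjusted p = 0.000208, 0.00674 and 0.00921). The macrophage and lymphocyte calls were lost with the share of reads outside genes as a covariate (-0.56 and -1.07, adjusted p = 0.153 and 0.0545). Camera called all 3 lists lower, but with an estimated correlation the adjusted p was 0.218, 0.465 and 0.465. Neutrophil genes, with 5 of 11 lower (6 adjusted over the list alone), gave a score difference of -0.88 (exact permutation p = 0.0411, adjusted p = 0.074). They were called with members scaled to equal variance (adjusted p = 0.03115, from a score difference of -0.70).

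Markers of tissues that may surround a tumour varied widely between tumours of the same group. Skeletal muscle scores were 4.09 ± 3.01 (SD, n = 6) in mitfa tumours and 3.26 ± 2.82 (SD, n = 12) in sox10 tumours, with 1 of 27 members, smyhc1, a slow muscle myosin, lower (0 adjusted over the list alone) and 26 not called (exact permutation p = 0.57). Without mitfa tumour 5, smyhc1 was no longer called (log2 fold change -1.21, edgeR adjusted p = 0.389). Epidermal scores were 4.36 ± 2.39 and 3.11 ± 1.56 (exact permutation p = 0.194). Of all 18731 genes tested 4190 were lower, and of 26 epidermal members 7 fell, also adjusted over the list alone. Among these was cdh1, the epithelial cadherin, which fell from 330 ± 145 to 13.7 ± 14.6 CPM. Among mitfa tumours cdh1 did not follow the epidermal score, with 410 and 497 CPM in mitfa tumours 1 and 5, which scored 1.38 and 1.32. The other mitfa tumours had 137.5 to 455.5 CPM and scores of 5.28 to 6.68. Among sox10 tumours cdh1 and the score were both highest in tumour 6 (51.3 CPM, score 5.84) and lowest in tumour 4 (1.03 CPM, score 0.61). Sox10 tumour 6 scored above mitfa tumours 1 and 5 yet had less cdh1. The fall of cdh1 between the groups is thus not read as a measure of adjoining epidermis, although cdh1 followed the score within sox10 tumours. Without mitfa tumours 1 and 5, an omission chosen after seeing the data, the epidermal score difference was -2.76 (exact permutation adjusted p = 0.0111). In the fibroblast and matrix list 12 of 23 fell (13 adjusted over the list alone), such as SPARC, a matrix glycoprotein, from 550 ± 380 to 132 ± 62.7 CPM, with a score difference of -0.85 (exact permutation p = 0.133). The call of SPARC was lost with the share of reads outside genes as a covariate (log2 fold change -1.26, edgeR adjusted p = 0.108). With a tumour left out the score difference was -1.33 to -0.44, the former without mitfa tumour 3 (exact permutation adjusted p = 0.0215), and without mitfa tumours 1 and 5 it was -0.17 (adjusted p = 0.913). Camera called the epidermis and fibroblast lists lower (adjusted p = 0.0442 for both), but not with an estimated correlation (adjusted p = 0.788 for both). The endothelial, erythrocyte, adipocyte and bone lists had score differences of 0.04, 0.04, -0.41 and 0.01 (exact permutation p = 0.887, 0.93, 0.105 and 0.986). Median fold changes of the endothelial and bone members had the opposite sign (-0.11 and -0.38). Called members were tek, an endothelial receptor (0 of 18 adjusted over the list alone), and ADIPOQ (ENSDARG00000062228), an adipocyte hormone (1 of 7 also over the list alone), both lower. In the bone list 2 of 16 were higher, such as COL2A1 (ENSDARG00000069093), and 4 lower, such as the osteoclast protease CTSK, also adjusted over the list alone. The more abundant COL2A1 copy (ENSDARG00000011407) was among the lower ones (log2 fold change -2.57, edgeR adjusted p = 0.000882). None of 11 erythrocyte genes was called by edgeR or limma and 1 by DESeq2, and 1 had an unadjusted p under 0.05 in edgeR. Without mitfa tumour 4 tek was no longer called (log2 fold change -0.80, edgeR adjusted p = 0.0532).

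No score of the energy metabolism and translation lists passed the threshold. In the hypoxia and glycolysis list 6 of 28 rose and 5 fell (6 and 4 adjusted over the list alone). BNIP3, a mitophagy receptor induced by hypoxia, rose by a log2 fold change of 3.03, and the phosphofructokinase PFKP (ENSDARG00000012801) fell by 1.94 on that scale. Its score differed by -0.04 (exact permutation p = 0.862) and its mean fold change was 0.02. Nuclear genes of oxidative phosphorylation fell in 6 of 24 cases (3 adjusted over the list alone), with SDHB, a subunit of complex II, at -0.76 on the log2 scale, but not called with the share of reads outside genes as a covariate (-0.52, edgeR adjusted p = 0.127). The score of these genes differed by -0.31 (exact permutation p = 0.0312, adjusted p = 0.0603), and by -0.45 without mitfa tumour 4 (adjusted p = 0.00145). Leaving out sox10 tumour 1, 3 or 6 also brought this call, as did RLE factors (adjusted p = 0.0474). Of 33 ribosomal protein genes 5 fell, and 0 adjusted over the list alone (score difference -0.38, exact permutation p = 0.144). None of 13 mitochondrially encoded genes was called by edgeR, DESeq2 or limma, and 0 had an unadjusted p under 0.05 in edgeR (score difference -0.22, exact permutation p = 0.334). Camera called the oxidative phosphorylation and ribosomal lists lower (adjusted p = 0.0442 and 0.0256), but not with an estimated correlation (adjusted p = 0.788 for both). Heat shock and early response genes fell in 10 of 26 cases and rose in 2, also adjusted over the list alone, with ier2a, an immediate early gene, from 157 ± 101 CPM (SD, n = 6) to 24.9 ± 14.2 CPM (SD, n = 12). That score differed by -0.60 (exact permutation p = 0.0091, adjusted p = 0.0189), and by -0.51 without mitfa tumour 2 (adjusted p = 0.0631). Leaving out mitfa tumour 3 or 4 ended this call too. The camera adjusted p of that list was 0.0439, and 0.465 with an estimated correlation.

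Over all genes tested, sox10 tumours lay closer to their group mean than mitfa tumours, though the exact permutation p was not under 0.05 in every alternative. The root mean squared distance of a tumour from the mean of its own group was 1.09 ± 0.151 log2 CPM (SD, n = 6) in mitfa tumours and 0.911 ± 0.072 log2 CPM (SD, n = 12) in sox10 tumours, a difference of -0.18 (2-sided exact permutation p = 0.0035). Over the 500 most variable genes the difference was -0.29 (exact permutation p = 0.111). Without mitfa tumour 1 it was -0.13 (exact permutation p = 0.0784). With sox10 tumours 9 and 10 as 1 library it was -0.178 over all genes (exact permutation p = 0.00461). These permutations kept the distances from the real group means, so the p-values are approximate.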

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

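The tests of brain or spinal cord tissue, of leukocytes and of the similar pair of sox10 tumours were chosen after the results they bear on were seen. The lists of oligodendrocyte lineage and transmitter neuron genes were likewise written after most of their members' values had been seen.

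Among 91 measures, list scores and named genes in the 6 mitfa tumours, 5 had a tumour far from the others. This is close to the share that chance gives, about 1 in 20. Mitfa tumour 4 had a neural crest score of 5.33 against 4.39 to 4.70 in the others, and a score for nuclear oxidative phosphorylation genes of 6.403 against 7.15 to 7.34. Its SOX9 (ENSDARG00000043923) level was 4.20 log2 CPM against 2.07 to 2.69, with 8.77 or more in all sox10 tumours. Mitfa tumour 2 had -3.10 log2 CPM of SOX1 (ENSDARG00000069866) against -2.12 to -1.64, which is 0 reads against at most 4. It had -2.55 log2 CPM of nlgn3b against -3.10, which is 1 read against 0. Sox10 tumours were not put to this test of single tumours.

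Oligodendrocyte lineage genes were high in sox10 tumours. OLIG2, a transcription factor of that lineage, had 23.8 ± 36.1 CPM (SD, n = 6) in mitfa tumours and 432 ± 125 CPM (SD, n = 12) in sox10 tumours. Brain or spinal cord tissue would bring transmitter neurons, but the summed CPM of SLC17A6, SLC17A7, SLC32A1, GAD1 and GAD2 was at the median 0.694% of OLIG2 and below it in 12 of 12 sox10 tumours (highest 55.7%, in tumour 7), while in mitfa tumours 1 and 5 it was 253% and 207%. Other neuronal genes went the other way, as ELAVL3 had 440 ± 151 CPM (SD, n = 12) in sox10 tumours and 13 of 14 neuronal list members rose. Neuron-rich tissue is argued against as the source of the whole pattern, on the evidence of the transmitter genes only, whose median sum was 2.52 CPM in sox10 tumours. In mitfa tumours 1 and 5 that sum was 146 and 168 CPM, although ELAVL3 had 0.464 and 0.820 CPM. A high sum alone therefore does not show neurons. Sox10 tumours 4 and 7 had sums of 105 and 256 CPM. A ratio to OLIG2 cannot exclude such tissue there if tumour cells make OLIG2 themselves, and no normal tissue was among the samples. Peripheral nerve would not bring MYRF, a regulator of central myelin genes with 1005 ± 369 CPM (SD, n = 12) in sox10 tumours. White matter without neuron bodies stays open, and no biological explanation was tested.

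Interferon response genes were lower in sox10 tumours. The interferon score minus the mean of the macrophage and lymphocyte scores was still lower by -1.07 (exact permutation p = 0.00178). Fewer leukocytes need not lower different lists equally, as 13 of 22 macrophage members fell and 2 rose. The subtraction therefore cannot decide whether fewer leukocytes account for the interferon difference. The high score of mitfa tumour 6 does not carry that difference, which was -1.72 without it (exact permutation p = 0.000162). The promoter, the cell of origin and the site of the tumour in the fish stay open and were not tested.

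Sox10 tumours 9 and 10 were nearly alike. A single library under both names is argued against, since the pair differed by 2.42 times sampling noise over 17804 genes. The next closest pair, sox10 tumours 4 and 7, differed by 16.5 times, so that samples of 1 tumour or 1 fish remain a candidate explanation. The labels do not say. Counted as 1 library, they left 3854 genes higher and 3985 lower in sox10 tumours.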

How the results depend on the processing

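The covariate of reads outside genes, the summing of sox10 tumours 9 and 10 and the omission of mitfa tumours 1 and 5 were chosen after seeing the data. Counts of called genes stayed within 1.5 times of 4024 higher and 4190 lower under DESeq2 (4449 and 4486), limma with quality weights (3619 and 3686), other factors, filters and tissue covariates, without mitfa tumours 1 and 5 (3806 and 4093), and with any tumour left out (3528 to 4017 higher, 3681 to 4217 lower). The median log2 fold change of all genes was -0.0331 with TMM factors. With reads outside genes as a covariate 2432 were higher and 2489 lower, of which 2249 and 2334 were called in that direction without it. The cause was not tested. The labels do not tie same-numbered tumours of the groups to each other. Deviations of same-numbered tumours correlated at 0.08, 0.13, 0.17, 0.15, -0.31 and -0.02. These values cannot decide on a pairing, as differently numbered tumours were not compared. A replicate block over the 12 tumours numbered 1 to 6 gave 2279 higher and 2216 lower, and the same 12 without the block 2539 and 3040, so that fewer samples account for part of the drop. Paired sign-flip tests over 6 pairs cannot go below 0.0312, and the 10 lists at that value had an adjusted p of 0.0844. At unadjusted p under 0.05 they kept 10 of the 13 lists called by score, and the p53 target, dedifferentiated and heat shock lists were not among them. By score, 4 lists were higher and 9 lower, with 3 to 4 and 7 to 10 over all alternatives and 8 to 11 lower with a tumour left out. With any tumour left out, 4 were higher. Camera called 3 lists higher and 11 lower, 3 and 10 with the replicate block, but 1 and 3 with an estimated correlation, which widens the null for lists whose members move together. Without mitfa tumours 1 and 5 the epidermis list was also called (score difference -2.76). Leaving out mitfa tumour 3 brought in the adipocyte list (-0.59, adjusted p = 0.0312), and leaving out sox10 tumour 1 or 3 the neutrophil list (-1.03 without tumour 3, adjusted p = 0.0265). The spread difference was -0.29 over the 500 most variable genes (exact permutation p = 0.111), where the cause was not tested, and -0.23 to -0.13 with a tumour left out, the latter without mitfa tumour 1 (exact permutation p = 0.0784). Of 60 named genes 47 kept their side of the threshold under each alternative that tested them, 12 lost a call under at least 1, BRAF gained one, and none reversed. RPL10, called with all tumours, was not called without mitfa tumour 3 (log2 fold change -0.60, edgeR adjusted p = 0.0648). With 200 changed genes among 18521 simulated ones, 2-fold changes were recovered in 23.2% of cases. The real comparison called 8214 genes, which makes the adjusted threshold less strict, so that share is no estimate of recovery here. A missing call still does not show that a gene was unchanged.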

Other observations

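The lists of Notch, lysosome, cholesterol and cilium genes were written after the main results and before their own were seen, and the genes named here were chosen after their values were seen. Notch pathway genes were higher in sox10 tumours, with 10 of 21 members higher and 2 lower in edgeR's test. Both copies of NOTCH1, a receptor, and of DLL1, a ligand, rose, while notch2 fell from 127 ± 97.6 CPM (SD, n = 6) to 29.7 ± 12.7 CPM (SD, n = 12) and the ligand dlc fell by 1.11 on the log2 scale. The score was 2.03 ± 0.402 in mitfa tumours and 3.88 ± 0.349 in sox10 tumours, a difference of 1.85 (exact permutation p = 5.39e-05, the smallest possible, adjusted p = 0.000215 over 4 lists). Lysosome genes fell in 12 of 28 cases and rose in 3, namely TFEB, NPC1 and a copy of MCOLN1. PSAP, a precursor of lipid-degrading cofactors, fell from 1769 ± 568 CPM (SD, n = 6) to 860 ± 260 CPM (SD, n = 12). The lysosome score differed by -0.35 (exact permutation p = 0.0178, adjusted p = 0.0357). The scores of macrophages and melanocytes, cells with many lysosomes or related organelles, were lower too (-0.77 and -6.48).

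The scores of cholesterol synthesis and cilium genes did not pass the threshold. Of 21 cholesterol genes 6 were higher and none lower in edgeR's test, with srebf2, the sterol-sensing regulator, at 48.9 ± 25.3 CPM (SD, n = 6) and 196 ± 176 CPM (SD, n = 12). The score difference of 0.93 did not pass (exact permutation p = 0.0801, adjusted p = 0.0994). Of 18 cilium genes 6 fell, such as BBS5, and 2 rose, rfx3 and RPGRIP1L, with a score difference of -0.18 (exact permutation p = 0.0994).

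Of 27 oligodendrocyte lineage genes, a list written after most values had been seen, 17 were higher and 2 lower, CSPG4 and cnp. NKX2-2, a transcription factor of that lineage, had 0.795 ± 0.117 CPM (SD, n = 6) in mitfa tumours and 505 ± 157 CPM (SD, n = 12) in sox10 tumours, and MYRF, a regulator of central myelin genes, 1.66 ± 0.299 and 1005 ± 369 CPM. No member of this list stands in the Schwann and glia list. OLIG2 reached 57.8 and 80.9 CPM in mitfa tumours 1 and 5 and at most 1.25 CPM in the other 4, where transmitter neuron genes summed to 146 and 168 CPM in the former and at most 6.18 CPM in the latter. In mitfa tumours 1 and 5 ELAVL3 had 0.464 and 0.820 CPM. The neuronal list scores of these tumours were -0.62 and -0.61, within the range of the other 4. Their high transmitter sums thus came without a higher neuronal score. In sox10 tumours the transmitter neuron genes summed to 256 CPM in tumour 7, 105 CPM in tumour 4 and 36.2 CPM in tumour 6, and to at most 12.3 CPM in the other 9.

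Splits of the 18 tumours into 6 and 12 by chance do not account for the count of called genes. The real split called 8214 genes, and the highest of 99 other splits drawn at random called 24, so 1 of 100 splits reached the real count.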
